A study of Rattus norvegicus with 12 samples.

How the data were processed

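Gene expression was measured by sequencing of total RNA from rat kidneys of a Zucker/Spontaneously Hypertensive Heart Failure strain cross. Per the labels' protocols, RNA was extracted with Trizol, fragmented with RNase III and turned into libraries by reverse transcription with SOLiD adaptors. RNase III cleaves double-stranded RNA, so fragment yield can differ between transcripts. Whether fragmentation differed between the groups was not examined. The labels list 12 samples in 3 groups, and the 10 libraries analysed here are obese surgery replicates 1 to 4, obese sham replicates 1, 2 and 3, and wild type sham replicates 2, 3 and 4. Obese sham replicate 4 and wild type sham replicate 1 were not analysed here. The labels do not name the operation, and it is called surgery throughout.

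The deposited files hold, for each gene model, a raw read count and an RPKM value (reads per kilobase of the model, relative to a library scale). Per the submitters' processing notes and the file headers the genome build was rn4. The aligner, its version and the read filters are not given in the sources used here. Per the file headers, reads with several positions were handled by a setting called partial, and RPKM was scaled with a setting called quartile. The deposited RPKM equals the count divided by the model's length and by a scaling count given in each header, in the units RPKM implies, with a largest difference of 1.8e-07 between the count and the count rebuilt from RPKM. That scaling count lay within 0.384% of the summed counts of gene models at or under the 75th percentile of models with a count. It made up 16% to 20.3% of each library's total, so the authors' RPKM values are several-fold higher than RPKM on all reads, and high-abundance genes do not enter their scale. Whether counting used strand is not given in the sources used here, so reads of genes overlapping on either strand cannot be told apart.

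The design written before the data were examined assumed RPKM with limma and named a test on counts as its replacement if the files held whole-number counts. They did, so every comparison was made on the deposited counts with edgeR. Each file lists 16527 gene models under 16386 symbols. For the 137 symbols with more than 1 model, the model with the highest mean RPKM was used and 141 models were left out. Genes passing filterByExpr (minimum count 10, minimum total count 15) with a mean RPKM of at least 0.5 were tested, which kept 11089 genes holding 99.9% of the counts and left out 5297. Libraries were scaled with TMM factors, and levels are given as CPM, counts scaled to the library total times its TMM factor. One edgeR quasi-likelihood model with the 3 groups and no other term was fitted to the 10 libraries, with a common biological coefficient of variation of 17.2%. The 3 comparisons were obese sham against wild type sham, obese surgery against obese sham, and obese surgery against wild type sham, each two-sided with Benjamini-Hochberg (BH) adjustment over the genes tested and a threshold of 0.05. An F test over the 3 groups was made from the same model. Every adjusted p of a gene is from this edgeR quasi-likelihood test with BH adjustment unless another tool is named. Errors of log2 fold changes are standard errors worked back from the change and its F statistic. For genes with few counts in a group they can be smaller than the counting error, which the ratio intervals cover. The p-values cover the spread among these libraries. The labels' design text calls the samples independent.

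The gene lists were written before the data were examined: 30 lists of kidney and other cell types and of pathways, of which 28 had at least 5 measured members. They were tested with camera from limma at an inter-gene correlation of 0.01, with BH adjustment over 84 tests, and again with the correlation estimated from the data. No list call held with the estimated correlation in any of the 3 comparisons. The genes named in the text were also chosen by a rule written before the data were examined. It takes Lepr in every comparison. For each of the first 2 comparisons it takes the 10 genes with the largest change in each direction among those past the threshold, with a group mean of at least 1 RPKM and no overlap between the groups' libraries, filled to 5 per direction with genes of smallest p where fewer passed. For the third comparison it takes 5 per direction, and from each list 2 members with the smallest p in each of the first 2 comparisons. Genes named only by a number were counted but not named, and not every gene that the rule selects is reported here. Genes outside this rule are named only as members of a list or family, as overlapping models, or in the androgen and mixing tests below.

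Total counts per library ran from 4758527 to 9444058, so 3 counts, taken as the detection floor of a library, correspond to 0.323 to 0.625 CPM. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. On simulated counts with known changes, the test of obese sham against wild type sham (10985 genes run) recovered 14.9% of genes changed 1.5-fold, 59.1% of those changed 2-fold and 93.8% of those changed 4-fold, with 1.72% false calls. For obese surgery against obese sham (10988 genes run) the shares were 20.9%, 69.7% and 95.4%, with 6.94% false calls. For obese surgery against wild type sham (10987 genes run) they were 32.8%, 66.7% and 98.5%, with 8.97% false calls. The simulated genes were independent and had the same dispersion in every group. The obese surgery libraries were more spread than that, so the shares recovered in their comparisons may be too high. No pair of libraries within a group had near-equal counts: chi-square per degree of freedom over genes was 8.45 or higher for every pair.

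Alternatives tried were median-of-ratios scaling, no filter on low counts, a mean RPKM of at least 2, counts summed over the models of a symbol, the replicate number as a block, DESeq2, limma on log2(RPKM + 0.5) and with pseudocounts of 0.1 and 1, limma without its trend, with robust moderation and array weights, with quantile normalization and with median-of-ratios scaling, a fit of only the groups compared, and each library left out in turn. Scaling by the count in the file headers, robust quasi-likelihood moderation, a correction for coding length, and a fit without obese surgery replicates 2 and 3 together were added after seeing the data. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. No rn4 genome or annotation was used, and coordinates are the 1-based rn4 positions of the deposited gene models. Gene models overlapping another, or with near-identical counts (summed differences over libraries under 10% of the gene's count) to a model that overlaps or shares a name stem, are named as uncertain where they are reported.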

Results

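Kidney transcript levels were compared among 3 groups of rats from a cross of the Zucker and Spontaneously Hypertensive Heart Failure strains. Zucker-derived obese rats carry leptin receptor mutations and develop obesity with kidney disease, and the strain adds hypertension and heart failure. The groups were obese rats after surgery (4 libraries), obese rats after a sham operation (3 libraries) and wild type rats after a sham operation (3 libraries). The type of surgery is not given in the sources used here. Total counts ran from 4758527 in obese sham replicate 3 to 9444058 in obese surgery replicate 3. The 10 genes with most counts took 10.3% to 10.8% of counts in the wild type libraries and 5.34% to 7.38% in the obese libraries. TMM factors were 0.894 to 0.908 in the wild type libraries.

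Libraries separated mainly by the obese phenotype. The first principal component of log2 CPM carried 51.5% of the variance and placed the wild type sham libraries at 38.6 to 41.1 and the obese sham libraries at -31.6 to -16.4. The obese surgery libraries were spread along it, with replicate 2 at -40.9, replicate 1 at -23.3, replicate 4 at -2.57 and replicate 3 at 11, nearest to the wild type libraries. The second component carried 10.4%. The leukocyte and tubular injury lists followed the same spread: mean levels relative to wild type sham were 1.71 and 2.46 log2 units in obese surgery replicate 2 and 0.27 and 0.088 in replicate 3, against 1.11 to 1.92 and 1.08 to 1.81 in the obese sham libraries.

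**Figure D1:**
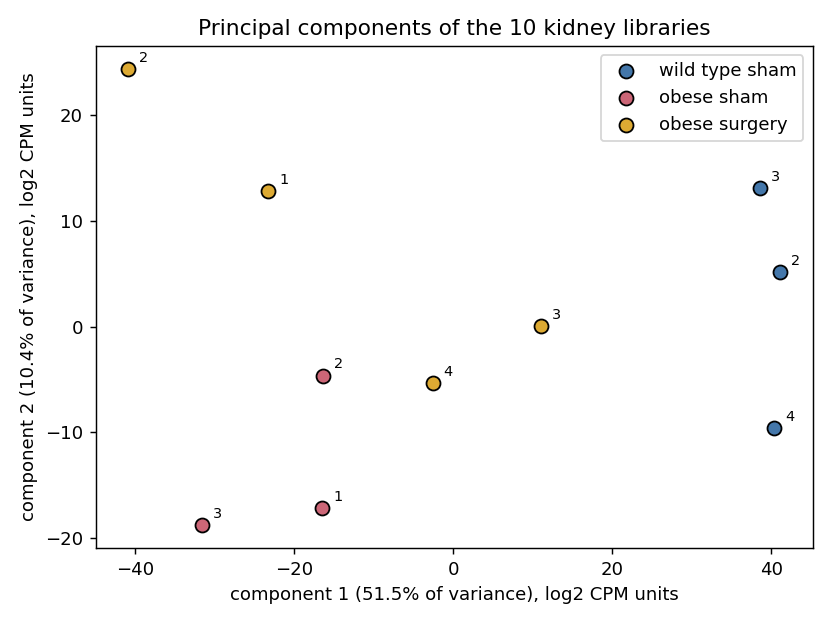
Scores of the 10 libraries on the first and second principal components of log2 CPM, one point per library, coloured by group. Wild type sham libraries lie at 38.6 to 41.1 on the first component, obese sham libraries at -31.6 to -16.4, and obese surgery libraries from -40.9 to 11.

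The first comparison, obese sham against wild type sham, asks what differs in the kidney with the obese phenotype when neither group had the operation. Lists of leukocyte, antigen presentation, inflammatory, matrix and tubular injury genes had higher medians in obese kidneys, and lists of transporter, renin-angiotensin and protein folding genes lower medians. With camera, 16 of 28 lists passed at an inter-gene correlation of 0.01 and 0 with an estimated correlation. Nos2, the inducible nitric oxide synthase of activated macrophages, was at 9.07 ± 2.1 CPM (SD, n = 3) in obese sham kidneys and had 1 count in all wild type libraries together. Cyp8b1, a sterol hydroxylase of bile acid synthesis, was at 49.3 ± 12 CPM (SD, n = 3) in wild type and 0.427 ± 0.061 CPM (SD, n = 3) in obese sham kidneys. Of 11089 genes, 478 rose and 496 fell, and 309 and 220 of these changed more than 2-fold. The groups' libraries did not overlap for 33.9% of genes, where chance gives 10%.

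Genes with the largest rises included enzymes and mediators of inflammation and matrix breakdown, all near the detection floor in wild type kidneys. Nos2 (rn4 chromosome 10, 65036884 to 65072453) rose by 6.84 ± 0.64 on the log2 scale (adjusted p = 0.000315, edgeR quasi-likelihood test with BH adjustment), a ratio of counts per library size of 154 with a 95% counting interval of 27.2 to 6130. Mmp13, a collagenase (chromosome 8, 4158887 to 4169166), rose by 6.78 ± 0.94 (edgeR adjusted p = 0.0023; ratio 123, interval 33.6 to 1020). Irg1, the itaconate-producing enzyme of activated macrophages (chromosome 15, 87056688 to 87066471), rose by 5.79 ± 0.77 (edgeR adjusted p = 0.00184; ratio 64.7, interval 17.6 to 540). The matrix protease Mmp7 went from 0.304 ± 0.12 to 43.2 ± 38 CPM (SD, n = 3 each; edgeR adjusted p = 0.00523). These 4 genes stayed past the threshold without any single library. Ratios were 102 for the hydrogen peroxide-producing oxidase Duox2 (interval 34.7 to 499), 116 for Clca1 (20.4 to 4630), 92.5 for the cytokine gene Il1a (16.2 to 3690) and 65.8 for the complement receptor gene Cr2 (11.4 to 2640), with edgeR adjusted p between 0.0137 and 0.0198. Duox2, Clca1 and Il1a did not pass without obese sham replicate 3 (0.0516, 0.0743 and 0.0558). Nor did they without wild type sham replicate 2 (0.0539, 0.0794 and 0.0625), 3 (0.0612, 0.075 and 0.0617) or 4 (0.0578, 0.0748 and 0.0569), and Cr2 did not pass without wild type sham replicates 2 or 3 (0.057 and 0.056). Tnn, encoding tenascin N, had no count in wild type kidneys and was at least 36-fold higher in obese sham kidneys, taking 3 counts over the wild type group as the floor (edgeR adjusted p = 0.0494). It had 18.1 CPM in obese sham replicate 3 against 0.656 and 2.61 CPM in replicates 1 and 2. Tnn did not pass without obese surgery replicates 1 or 4, obese sham replicates 2 or 3, or wild type sham replicates 2, 3 or 4, with adjusted p from 0.0611 to 0.141. S100a9, a calprotectin subunit of neutrophils, rose by 5.81 ± 1.60 (edgeR adjusted p = 0.0451). It did not pass without obese surgery replicate 1 (0.0523), obese sham replicates 1, 2 or 3 (0.0686, 0.0822 and 0.119) or wild type sham replicates 2, 3 or 4 (0.132, 0.116 and 0.13).

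The 10 largest falls included transporters and metabolic enzymes. Cyp8b1 (chromosome 8, 127018908 to 127020878) fell by 6.77 ± 0.49 on the log2 scale and Serpinb12, a serine protease inhibitor (chromosome 13, 13106080 to 13137360), by 6.19 ± 0.45, both with an edgeR adjusted p of 5.52e-05. Slc7a12, of an amino acid transporter family, went from 616 ± 160 to 17.3 ± 6.4 CPM, the organic anion transporter Slco1a1 from 650 ± 82 to 24.8 ± 6.0 CPM, and the male-specific steroid hydroxylase of liver Cyp2c11 from 182 ± 110 to 5.18 ± 2.0 CPM (SD, n = 3 each). Their log2 changes were -5.15 ± 0.52, -4.72 ± 0.67 and -5.16 ± 0.90. The model of Slc7a12 overlaps Lrrcc1, and that of Slco1a1 overlaps Slco1a5 and Slco1a6, so reads may be shared between them. Cftr, the epithelial chloride channel, fell by 4.45 ± 0.39 (edgeR adjusted p = 0.000227) from 62.9 ± 13 CPM (SD, n = 3). The annexin gene Anxa13, the aldehyde dehydrogenase gene Aldh1b1, the olfactory receptor gene Olr1331 and the defensin gene Defb42 changed by -5.36, -4.11, -4.09 and -4.18, with edgeR adjusted p of 0.000637, 0.00181, 0.0107 and 0.00962. Olr1331 did not pass without obese sham replicate 1 (0.0538). Defb42 had 2 counts in obese sham kidneys, a ratio of 20.9 with an interval of 5.45 to 178. Lepr, the leptin receptor gene (chromosome 5, 122320075 to 122503437), was at 18.4 ± 5.6 CPM in wild type and 20.4 ± 2.4 CPM in obese sham kidneys (SD, n = 3 each; log2 change 0.14 ± 0.26, edgeR adjusted p = 0.777). Its model overlaps Leprot on the same strand, and its level says nothing of a point mutation.

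Of 17 leukocyte and macrophage markers, 13 rose over all genes and 15 adjusted over the list alone, with a median log2 change of 1.45 (camera adjusted p = 8.58e-15; adjusted p = 0.45 with an estimated correlation). Csf1r, the macrophage growth factor receptor gene, went from 48.8 ± 2.5 to 149 ± 31 CPM (SD, n = 3 each), and the pan-leukocyte gene Cd53 from 12.5 ± 1.8 to 66.6 ± 28 CPM. Antigen presentation genes had a median of 0.94, with 7 of 15 higher and 1 lower (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.35e-08; adjusted p = 0.45 with an estimated correlation). The class II genes RT1-Bb and RT1-Ba rose by 1.79 ± 0.24 and 1.81 ± 0.26, while the class I gene RT1-A1 fell. The chemokine and inflammatory list had 7 of 18 genes higher (11 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 1.15e-07; adjusted p = 0.45 with an estimated correlation). Among them was the pattern receptor gene Tlr2 at 1.99 ± 0.38. Complement and coagulation genes had 6 of 21 higher (8 higher and 1 lower adjusted over the list alone; median 0.72, camera adjusted p = 0.000394; adjusted p = 0.45 with an estimated correlation), with complement factor I, Cfi, at 3.08 ± 0.50. Interferon response genes had 3 of 19 higher, also adjusted over the list alone (median 0.28, camera adjusted p = 0.0229; adjusted p = 0.45 with an estimated correlation), with the transcription factor gene Irf1 at 1.39 ± 0.27. The list did not pass without obese sham replicate 1 (median 0.17, interferon response genes adjusted p = 0.317) or wild type sham replicate 4 (0.0561), nor with quantile normalization (0.0717).

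The lists of matrix, injury and proliferation genes had higher medians in obese sham kidneys. Of 19 extracellular matrix and fibrosis genes, 3 rose (9 adjusted over the list alone; median 0.94, camera adjusted p = 8.47e-06; adjusted p = 0.45 with an estimated correlation), with Postn, encoding periostin, at 5.09 ± 0.93. Postn was at 96.1 CPM in obese sham replicate 3 against 9.51 and 19.7 CPM in replicates 1 and 2, and without replicate 3 its log2 change was 3.59 (edgeR adjusted p = 0.0168). Of 15 tubular injury genes, 3 rose (8 adjusted over the list alone; median 1.30, camera adjusted p = 9.67e-06; adjusted p = 0.45 with an estimated correlation), with Gpnmb, a glycoprotein of macrophages and injured epithelium, at 3.04 ± 0.55. Havcr1, the injury marker KIM-1, was at 17.2 ± 11 and 144 ± 70 CPM (SD, n = 3 each; edgeR adjusted p = 0.11), which did not pass. Of 16 cell cycle genes, 3 rose (6 adjusted over the list alone; median 1.11, camera adjusted p = 4.3e-05; adjusted p = 0.45 with an estimated correlation), including the replication gene Top2a at 1.61 ± 0.35. Top2a did not pass without obese sham replicate 3 (0.0741) or wild type sham replicates 2 or 3 (0.0752 and 0.0602). In the erythroid and blood list, 1 of 6 rose (4 adjusted over the list alone; median 1.52, camera adjusted p = 0.00216; adjusted p = 0.45 with an estimated correlation), and that gene was S100a9.

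Several lists of tubular transport and metabolism had lower medians, past the threshold at a correlation of 0.01 and not with an estimated correlation. In the list of organic anion, cation and amino acid transporters, 7 of 18 fell (8 adjusted over the list alone; median -0.35, camera adjusted p = 2.96e-05; adjusted p = 0.45 with an estimated correlation), among them the peptide transporter gene Slc15a2 at -1.35 ± 0.19. Of 16 proximal tubule markers, 4 fell (5 adjusted over the list alone; median -0.29, camera adjusted p = 0.000713; adjusted p = 0.525 with an estimated correlation). Slc7a13, an amino acid transporter of the straight proximal tubule (chromosome 5, 34417523 to 34438072), went from 7456 ± 1226 to 951 ± 203 CPM (SD, n = 3 each), and its partner Slc3a1 fell by 1.49 ± 0.17. Renin-angiotensin-aldosterone genes had 5 of 12 lower (7 adjusted over the list alone; median -0.83, camera adjusted p = 3.57e-06; adjusted p = 0.45 with an estimated correlation), including the peptidase gene Anpep at -1.55 ± 0.21 and the angiotensinogen gene Agt at -1.22 ± 0.18. Unfolded protein response genes had 6 of 14 lower (8 adjusted over the list alone; median -0.44, camera adjusted p = 6.85e-05; adjusted p = 0.45 with an estimated correlation), with the chaperone gene Hspa5 at -1.06 ± 0.19. Cytochrome P450 and steroid metabolism genes had 5 of 19 lower and 1 higher (7 and 1 adjusted over the list alone; median -0.16, camera adjusted p = 0.0149; adjusted p = 0.45 with an estimated correlation), with Cyp2d1 at -1.96 ± 0.26. Of 28 fatty acid oxidation and PPAR target genes, 4 fell, also adjusted over the list alone (median -0.22, camera adjusted p = 0.00697; adjusted p = 0.546 with an estimated correlation). The fatty acid omega-hydroxylase gene Cyp4a2 was at 19496 ± 2268 and 5676 ± 1069 CPM (SD, n = 3 each; -1.78 ± 0.25). Cyp4a3, whose counts were below those of Cyp4a2 in every library, fell by 1.74 ± 0.25. Levels of Cyp4a2 and Cyp4a3 moved together across libraries and reads with several positions may be shared, so these falls may not be separate. The model of Cyp4a2 overlaps Cyp4a8, so reads of Cyp4a2 and Cyp4a8 cannot be told apart. Cyp4a2 did not pass with limma on log2(RPKM + 0.5) (-1.79, adjusted p = 0.0618), and with quantile normalization Cyp4a2 and Cyp4a3 differed by -0.54 and -0.84 (limma adjusted p = 0.514 and 0.124). Of 42 oxidative phosphorylation genes 1 fell, cytochrome c (Cycs), and 0 adjusted over the list alone by edgeR. The list median was -0.18 (camera adjusted p = 0.0076; adjusted p = 0.751 with an estimated correlation). Without obese sham replicate 2 the oxidative phosphorylation genes had a median of -0.098 and an adjusted p of 0.152, and with the length-trend correction an adjusted p of 0.0804. With quantile normalization 4 of these lists did not pass: proximal tubule markers (median 0.009, camera adjusted p = 0.367), fatty acid oxidation and PPAR target genes (0.73), oxidative phosphorylation genes (median 0.051, 0.748) and cytochrome P450 and steroid metabolism genes (0.155, and 0.0504 with robust limma).

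The remaining lists did not pass. Adjusted p with camera was 0.244 for podocyte, 0.076 for loop of Henle, 0.904 for collecting duct, 0.904 for endothelial, 0.717 for adipocyte and 0.826 for muscle genes. It was 0.0543 for fatty acid and cholesterol synthesis, 0.557 for glucose handling, 0.239 for Nrf2 target, 0.118 for immediate early, 0.792 for circadian clock and 0.351 for phosphate, calcium and acid-base transport genes. The collecting duct and muscle lists had medians of -0.18 and -0.042 and a camera direction of higher, and the endothelial list a median of 0.048 and a mean of -0.0026. Within these lists single genes changed in both directions: 3 phosphate, calcium and acid-base transport genes rose and 1 fell, 2 Nrf2 target genes rose and 3 fell, 1 loop of Henle gene rose and 2 fell, and 1 adipocyte gene rose and 1 fell. In the collecting duct, muscle and immediate early lists 1 gene each rose, and in the synthesis list 1 fell. Among those that fell, Umod, encoding uromodulin of the thick ascending limb, fell by 1.42 ± 0.21. The glutathione synthesis genes Gclc and Gclm fell by 1.87 ± 0.28 and 1.48 ± 0.23, and malic enzyme 1, Me1, by 1.73 ± 0.22. Adrenal and urothelial markers, with 2 and 3 genes measured, were not tested as lists. None of these genes passed over all genes, and 1 adrenal gene was lower adjusted over the list alone.

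The smallest edgeR quasi-likelihood adjusted p (BH) in this comparison was 5.52e-05, and 2879 genes (26%) had an unadjusted p under 0.05. The number of genes past the threshold depended on single libraries: 439, 594 and 377 genes without obese sham replicates 1, 2 and 3, 410, 465 and 549 without wild type sham replicates 2, 3 and 4, and 1504 without obese surgery replicate 2, whose spread enters the shared model. The balance of directions changed too, with 533 higher and 480 lower when scaled by the header count, 132 and 245 without obese sham replicate 3, and 141 and 269 without wild type sham replicate 2.

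**Figure D2:**
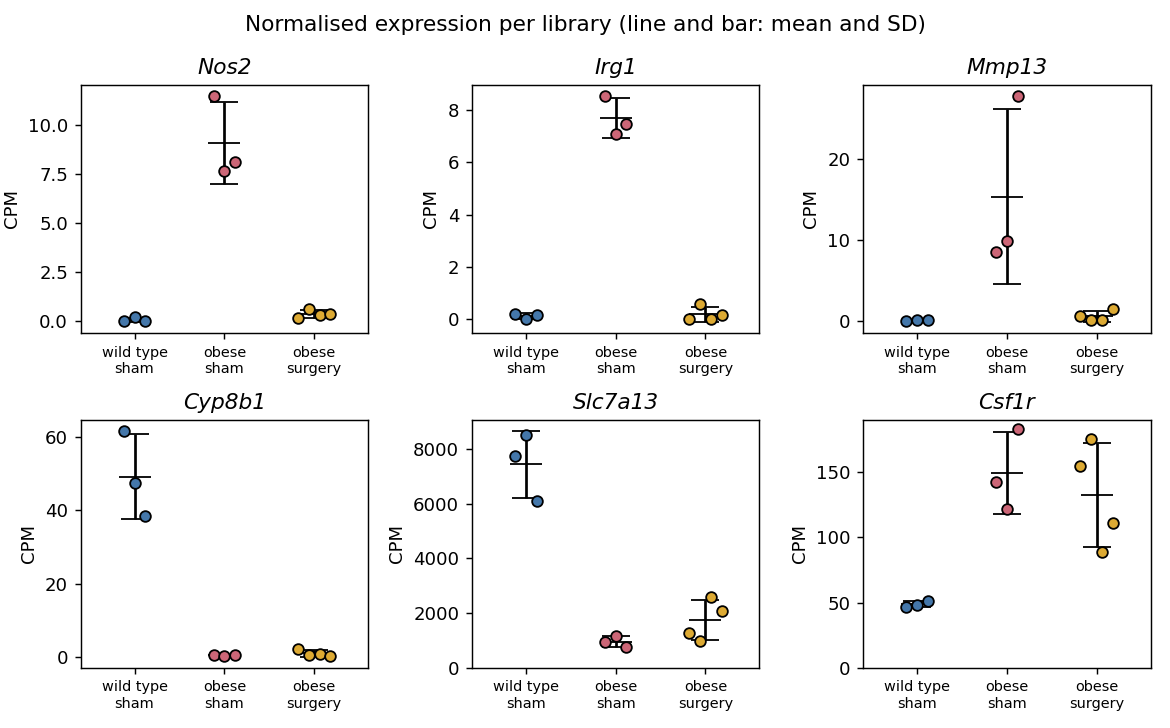
CPM of Nos2, Irg1, Mmp13, Cyp8b1, Slc7a13 and Csf1r in each of the 10 libraries, one point per library, with the mean ± SD of each group. Nos2, Irg1 and Mmp13 averaged 9.07, 7.69 and 15.4 CPM in obese sham kidneys and 0.35, 0.193 and 0.618 CPM after surgery, while Cyp8b1 averaged 49.3 CPM in wild type kidneys.

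The second comparison, obese surgery against obese sham, asks what the operation changed in obese kidneys. The genes Nos2, Irg1 and Mmp13, which were near the floor in wild type kidneys and high in obese sham kidneys, were low again in all 4 obese surgery libraries. Nos2 was at 0.35 ± 0.19 CPM (SD, n = 4) after surgery and fell by 4.65 ± 0.42 on the log2 scale (edgeR quasi-likelihood adjusted p = 0.00194, BH). Irg1 was at 0.193 ± 0.28 CPM (SD, n = 4) and fell by 5.32 ± 0.62 (edgeR adjusted p = 0.0127), and Mmp13 was at 0.618 ± 0.67 CPM (SD, n = 4) and fell by 4.72 ± 0.64 (edgeR adjusted p = 0.0396). These 3 genes were the only ones of 11089 past the threshold, so the edgeR test called 3 lower and 0 higher. DESeq2 called 4 lower and 1 higher, and limma on log2(RPKM + 0.5) 2 lower and 0 higher.

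Genes of smallest p that did not pass were Gcnt3, a mucin glycan-branching enzyme gene, at -3.67 ± 0.60 (edgeR adjusted p = 0.165) and Mmp7 at -3.96 ± 0.73 (edgeR adjusted p = 0.369). Those on the higher side, each with an edgeR adjusted p of 0.998, were the glycan-branching enzyme gene Gcnt1 at 0.64 ± 0.15, the immunophilin gene Fkbp2 at 0.45 ± 0.11, the renalase gene Rnls at 0.44 ± 0.12, Hmg1l1 at 0.43 ± 0.11 and Slc10a3 at 0.47 ± 0.13. Lepr was at 15.3 ± 4.6 CPM (SD, n = 4) after surgery, a log2 difference of -0.42 ± 0.24 from obese sham (edgeR adjusted p = 0.998). Slc7a13, lower in obese sham kidneys, was at 1742 ± 736 CPM after surgery (SD, n = 4; 0.87 ± 0.30, edgeR adjusted p = 0.998).

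At the level of lists, 9 passed, 3 higher and 6 lower, although no member of any list passed alone, over all genes or adjusted over the list alone, except 1 matrix gene adjusted over the list alone. Immediate early genes, transcribed within minutes of a stimulus, were higher by a median of 0.50 in 13 of 16 members (camera adjusted p = 7.82e-05; adjusted p = 0.45 with an estimated correlation), led by Egr1 at 1.70 ± 0.64 and Cyr61 at 1.01 ± 0.41. Without obese surgery replicate 4, where Egr1 was at 45.7 CPM, Egr1 differed by 0.89, the median was 0.22 and the adjusted p 0.0682. Renin-angiotensin-aldosterone genes were higher by 0.27 (10 of 12 members; camera adjusted p = 0.00106; adjusted p = 0.45 with an estimated correlation), with Agt at 0.37 ± 0.17. With limma without trend the renin-angiotensin-aldosterone genes had an adjusted p of 0.0501, and the call of proximal tubule markers given below was lost as well (0.0562). The unfolded protein response genes were higher by 0.15 in 14 of 14 members (camera adjusted p = 0.0126; adjusted p = 0.45 with an estimated correlation), but their adjusted p was 0.0722 without obese surgery replicate 4 and 0.12 without obese sham replicate 1.

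Leukocyte and macrophage markers were lower in 16 of 17 members (median -0.33, camera adjusted p = 9.16e-06; adjusted p = 0.45 with an estimated correlation), with the T cell gene Cd3e at -1.21 ± 0.40 and the adaptor gene Tyrobp at -0.79 ± 0.36. Without obese sham replicate 3 these were -0.75 and -0.43, and without obese surgery replicate 3 Tyrobp differed by -0.53. Antigen presentation genes were lower in 15 of 15 members (median -0.28, camera adjusted p = 2.93e-05; adjusted p = 0.45 with an estimated correlation). Both calls rested on obese surgery replicate 3: without it the medians were -0.12 and -0.10, with adjusted p of 0.124 and 0.136. Interferon response genes were lower (median -0.20, camera adjusted p = 0.00306; adjusted p = 0.45 with an estimated correlation), but with an adjusted p of 0.525 without obese sham replicate 1. Oxidative phosphorylation genes were lower in 35 of 42 members (median -0.11, camera adjusted p = 1.39e-05; adjusted p = 0.613 with an estimated correlation), but the median was 0.011 and the adjusted p 0.872 without obese surgery replicate 2. Fatty acid oxidation genes (median -0.10, camera adjusted p = 0.0269; adjusted p = 0.618 with an estimated correlation) had adjusted p of 0.187, 0.694 and 0.276 without obese surgery replicates 1 and 2 and obese sham replicate 1. Proximal tubule markers (median -0.22, camera adjusted p = 0.0269; adjusted p = 0.677 with an estimated correlation) had adjusted p of 0.188, 0.901 and 0.394 without the same 3 libraries, and of 0.0862 with quantile normalization.

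The other lists did not pass in this comparison. Camera adjusted p was 0.303 for podocyte, 0.0552 for loop of Henle, 0.46 for collecting duct, 0.808 for endothelial, 0.41 for adipocyte, 0.693 for erythroid and 0.433 for muscle genes. It was 0.725 for matrix, 0.717 for tubular injury, 0.764 for cell cycle, 0.741 for complement, 0.206 for chemokine, 0.633 for transporter and 0.592 for cytochrome P450 genes. It was 0.226 for fatty acid and cholesterol synthesis, 0.426 for glucose handling, 0.592 for Nrf2 target, 0.39 for circadian clock and 0.131 for phosphate, calcium and acid-base transport genes. The matrix list had a median of 0.035 and a mean of -0.17, and the tubular injury list a median of 0.17 with a camera direction of lower. The median and mean of the complement list were -0.015 and 0.19, and those of the transporter list -0.017 and 0.074. The cytochrome P450 list had a median of -0.009 and a mean of 0.17, and the endothelial list a median of 0.016 and a mean of -0.021.

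Of the tests of single genes, 407 (3.67%) had an unadjusted p under 0.05, and libraries did not overlap for 4.66% of genes, where chance gives 5.71%. Without obese sham replicates 1, 2 or 3 or wild type sham replicate 2, 1 gene passed. Nos2 stayed past the threshold without any single library, while Irg1 did not pass without obese surgery replicate 4 (edgeR adjusted p = 0.0539), obese sham replicates 1, 2 or 3 (0.0874, 0.0749 and 0.0808) or wild type sham replicate 2 (0.0552). Mmp13 passed without obese surgery replicate 4 (0.0357) and did not pass without obese surgery replicates 1, 2 or 3 (0.17, 0.0727 and 0.0883), obese sham replicates 1, 2 or 3 (0.0836, 0.0749 and 0.239) or wild type sham replicates 2, 3 or 4 (0.106, 0.126 and 0.116), and with limma on log2(RPKM + 0.1) no gene passed (0.751 for each of the 3).

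The third comparison, obese surgery against wild type sham, asks what remained different from wild type kidneys after the operation. Lists of leukocyte, matrix and tubular injury genes still had higher medians in obese kidneys after surgery, and lists of transporter, renin-angiotensin and fatty acid oxidation genes lower medians. Obese surgery replicate 3 showed little of these rises. Its mean levels relative to wild type sham were 0.271 for leukocyte, 0.0956 for matrix and 0.0884 log2 units for tubular injury genes. The wild type libraries lay at -0.117 to 0.202, -0.0873 to 0.0692 and -0.157 to 0.284. With camera, 16 of 28 lists passed at an inter-gene correlation of 0.01 and 0 with an estimated correlation. Cyp8b1 was at 0.939 ± 0.84 CPM (SD, n = 4) against 49.3 ± 12 CPM in wild type kidneys, a log2 change of -5.62 ± 0.37 (edgeR quasi-likelihood adjusted p = 3.15e-05, BH). Of 11089 genes, 541 rose and 602 fell, and 281 and 188 of these changed more than 2-fold. Libraries did not overlap for 24% of genes, where chance gives 5.71%.

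The largest rises included neutrophil and acute phase genes. S100a8, the other calprotectin subunit, rose by 6.72 ± 1.80 (edgeR adjusted p = 0.0378) and S100a9 by 5.97 ± 1.54 (0.0338), and S100a8 was at 112 CPM in obese surgery replicate 2 against 1.94 to 14.5 CPM in the other 3. Hp, the haptoglobin gene, rose by 6.17 ± 1.58 (edgeR adjusted p = 0.0325), with 71.9 CPM in replicate 1 and 2.07 to 14.7 CPM in the others. The neutrophil collagenase gene Mmp8 had a ratio of 77.1 to wild type (95% counting interval 13.6 to 3070) and the cytokine gene Il24 a ratio of 36.5 (9.91 to 305), with edgeR adjusted p of 0.0289 and 0.0295. None of these 5 passed without wild type sham replicate 2, 3 or 4, where their adjusted p was 0.0829 to 0.121. S100a8, S100a9 and Il24 did not pass without obese surgery replicate 1 (0.0577, 0.0511 and 0.0607), S100a8, S100a9 and Hp not without obese sham replicate 2 (0.0549, 0.0502 and 0.0501), and S100a8 not without obese sham replicate 1 (0.0521). Havcr1 rose by 4.66 ± 1.15 (edgeR adjusted p = 0.0285) and was at 1431 CPM in replicate 2 against 47.7 to 173 CPM in the others. Calls of Havcr1 and of Alas2 and Cyp4a2 below were not refitted under the alternatives for this comparison. The largest falls besides Cyp8b1 were in Serpinb12 (-5.08 ± 0.35), Olr1331 (-4.83 ± 0.73), Slc7a12 (-4.32 ± 0.43) and Anxa13 (-4.02 ± 0.44), each past the threshold without any single library. Lepr differed by -0.28 ± 0.25 (edgeR adjusted p = 0.491).

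Among the lists, 9 were higher and 7 lower than in wild type kidneys, each with an adjusted p of 0.45 with an estimated correlation except as given. Higher were leukocyte markers (8 of 17 genes, 14 adjusted over the list alone; median 1.19, camera adjusted p = 2.82e-09), tubular injury genes (8 of 15, 9 adjusted over the list alone; 1.52, adjusted p = 2.79e-05), matrix genes (5 of 19, 14 adjusted over the list alone; 1.04, adjusted p = 6.6e-06) and cell cycle genes (5 of 16, 8 adjusted over the list alone; 1.17, adjusted p = 1e-05). Higher too were chemokine genes (8 of 18, 11 adjusted over the list alone; 0.75, adjusted p = 9.34e-07), complement genes (9 of 21 and 1 lower, 12 and 1 adjusted over the list alone; 0.81, adjusted p = 0.000185) and antigen presentation genes (6 of 15 and 1 lower, 9 and 1 adjusted over the list alone; 0.61, adjusted p = 3.86e-05). Erythroid and blood genes were higher (3 of 6, 4 adjusted over the list alone; 1.25, adjusted p = 0.000815), led by S100a8, S100a9 and the heme synthesis gene Alas2. Immediate early genes were higher by a median of 0.89 (3 of 16, 9 adjusted over the list alone; adjusted p = 0.000362; adjusted p = 0.497 with an estimated correlation). In obese surgery replicate 3, mean levels of antigen presentation (0.0307) and immediate early genes (-0.0843) lay within the wild type libraries (-0.0656 to 0.126 and -0.207 to 0.296). Those of its cell cycle, chemokine, complement and erythroid lists (0.667, 0.385, 0.184 and 1.25) lay above them.

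Lower than in wild type kidneys were proximal tubule markers (5 of 16, also adjusted over the list alone; median -0.60, camera adjusted p = 2.24e-06), transporter genes (6 of 18, 9 adjusted over the list alone; -0.56, adjusted p = 2.3e-05) and oxidative phosphorylation genes (6 of 42, 9 adjusted over the list alone; -0.33, adjusted p = 1.4e-06; adjusted p = 0.546 with an estimated correlation). Fatty acid oxidation genes had 9 of 28 lower and 2 higher (13 and 3 adjusted over the list alone; -0.29, adjusted p = 5.04e-05), with Cyp4a2 at -1.82 ± 0.22. Renin-angiotensin-aldosterone genes had 4 of 12 lower (5 adjusted over the list alone; -0.28, adjusted p = 0.000496), unfolded protein response genes 4 of 14 (7 adjusted over the list alone; -0.32, adjusted p = 0.00325) and cytochrome P450 genes 5 of 19 with 1 higher (6 and 2 adjusted over the list alone; -0.28, adjusted p = 0.0146). Without obese surgery replicate 2 the cytochrome P450 and steroid metabolism genes had a median of -0.13 and an adjusted p of 0.104, and with quantile normalization 0.0862. Quantile normalization also ended the calls of the fatty acid oxidation and PPAR target genes (0.0862), oxidative phosphorylation genes (0.171) and unfolded protein response genes (0.435). Not past the threshold were the podocyte (0.0644), loop of Henle (0.349), collecting duct (0.809), endothelial (0.826), adipocyte (0.433), muscle (0.58), interferon (0.351), glucose handling (0.803), Nrf2 target (0.105), circadian clock (0.904), fatty acid and cholesterol synthesis (0.174) and phosphate, calcium and acid-base transport (0.807) lists, each with its camera adjusted p. The loop of Henle, endothelial, glucose handling, muscle and phosphate lists had a median and a mean of opposite sign.

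In this comparison 3207 genes (28.9%) had an unadjusted p under 0.05. The number of genes past the threshold was 317, 384 and 366 without wild type sham replicates 2, 3 and 4, 448 and 729 without obese surgery replicates 1 and 2, and 1832 without obese surgery replicate 3. The balance of directions changed too, with 654 higher and 510 lower when scaled by the header count, 96 and 221 without wild type sham replicate 2, and 980 and 852 without obese surgery replicate 3.

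**Figure D3:**
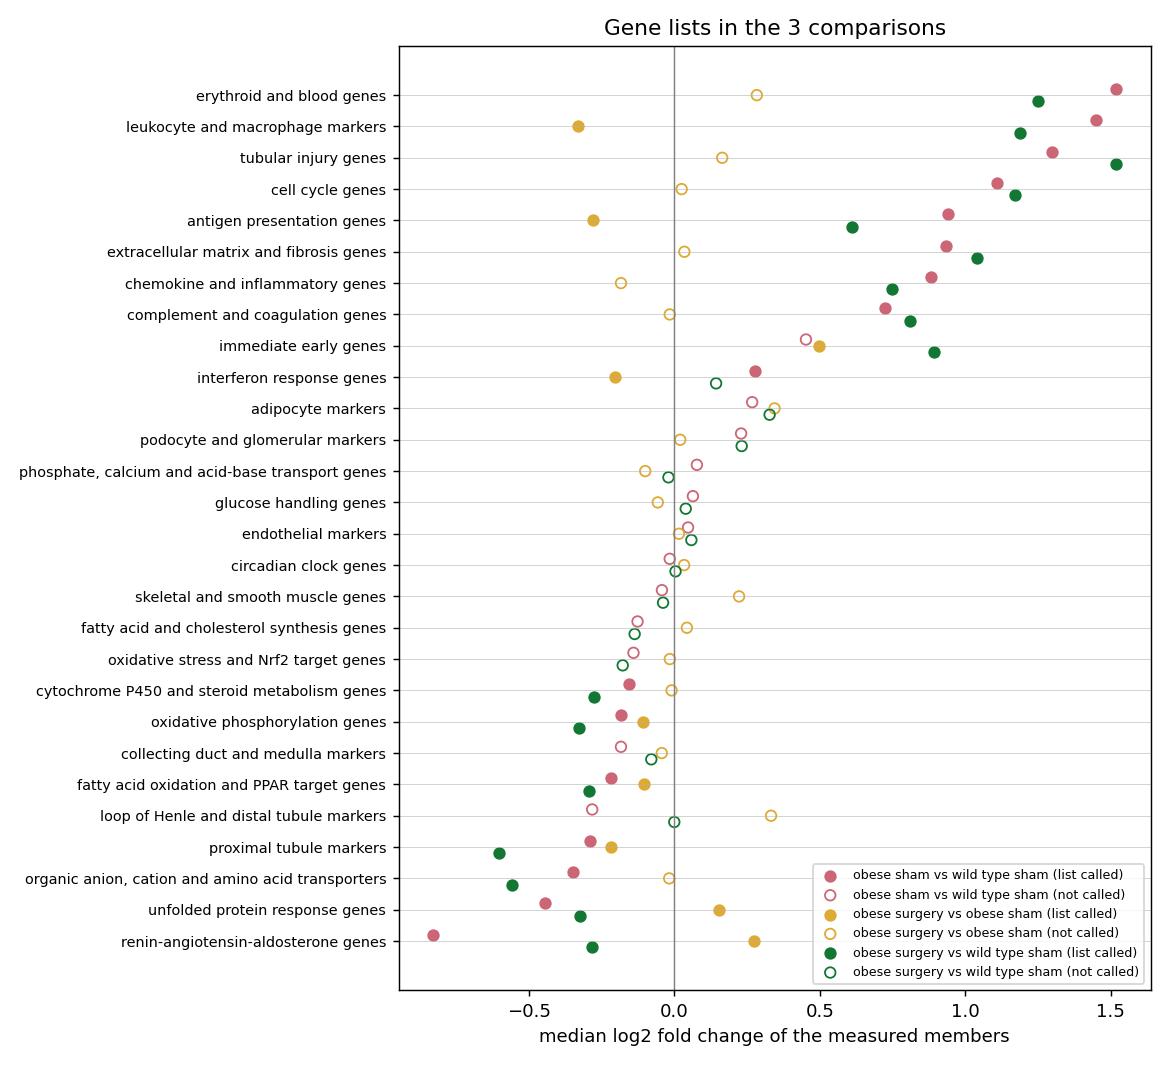
Median log2 fold change of the 28 tested gene lists in the 3 comparisons, one point per list and comparison, filled where the camera test passed at an inter-gene correlation of 0.01. Leukocyte markers lie at 1.45, -0.33 and 1.19 in the 3 comparisons and renin-angiotensin-aldosterone genes at -0.83, 0.27 and -0.28.

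Comparing the gene sets themselves, 312 genes were higher and 388 lower in both obese groups than in wild type sham, and 0 changed in opposite directions, against 23.3 and 26.9 for independent lists. Simulations of unchanged groups sharing the wild type libraries gave at most 1 and 0 in 100 runs. Another 274 genes passed in obese sham only and 443 in obese surgery only, which does not show a difference between the obese groups, since in the direct comparison 3 genes passed. The covariance of the fold changes across genes was 0.376 against a simulated 0.039, a difference of 0.337, with a correlation of 0.895 against 0.542. In 50 simulations that kept the obese effect and gave surgery none, 621 to 721 genes were higher and 573 to 642 lower in both groups, more than observed, with a correlation of 0.926 to 0.937 and a mean covariance of 0.452. Genes are not independent replicates. All these simulations drew each gene on its own, without changes that many genes share within a library. Their ranges are therefore likely too narrow, and a gap to the runs without a surgery effect does not show such an effect. The 3 wild type libraries could not be split into groups of at least 2, so part of the excess may come from the shared controls. The F test over the 3 groups passed for 813 genes (edgeR quasi-likelihood with BH adjustment). It passed for 226, 269 and 289 genes without wild type sham replicates 2, 3 and 4, for 491 and 499 without obese sham replicates 1 and 3, and for 1391 without obese surgery replicate 3.

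Of the 974 genes changed in obese sham kidneys, 81.5% (95% binomial interval 78.9% to 83.9%) had the opposite sign in obese surgery against obese sham. That interval treats genes as independent and does not cover the spread among libraries. Both comparisons use the obese sham libraries, so opposite signs arise without any effect. The share among the 974 top-ranked genes was 89.4% (86.3% to 92.6%) in 100 simulations of unchanged groups, and it was 66.8% (63.4% to 70.3%) in 50 simulations that kept the obese effect and gave surgery none. The covariance of the fold changes was -0.091 against a simulated -0.039, a difference of -0.052, with a correlation of -0.44 against -0.55. In the simulations that gave surgery no effect the correlation was -0.22 (-0.26 to -0.17) and the covariance -0.039. Here too each gene was drawn on its own, so the ranges leave out changes that many genes share within a library. A gap to them does not show an effect of surgery. Without obese surgery replicate 3 the share was 59.4%, and without obese sham replicate 1 it was 92.7%.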

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

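The tests of cell share, coding length, position between groups, mixing, single libraries and other splits were chosen after the result was seen. In 8 of 126 measures tested, 1 of the 4 obese surgery libraries stood far from the other 3, by the gap to its nearest neighbour as a share of the group's range. Chance does this in about 1 in 20 groups, and the measures are not independent.

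Obese surgery replicate 3 was lowest for 4 genes: Cr2 (gap 0.846 of the range; log2 CPM -0.9 against 0.938 to 1.27), Cftr (0.904; 1.91 against 2.98 to 3.1), and the class II genes RT1-Bb (0.964; 7.38 against 8.17 to 8.2) and RT1-Db1 (0.984; 6.36 against 7.27 to 7.29). Replicate 2 was lowest for Slc8a1 (0.897; 7.62 against 8.05 to 8.09). Replicate 4 was highest for Sgk1 (0.915; 10.1 against 8.76 to 8.88) and Ifit3 (0.857; 3.27 against 2.15 to 2.31). Replicate 1 was lowest for Calr (0.839; 9.42 against 9.49 to 9.51).

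Leukocyte markers were higher and transporter genes lower in obese sham than in wild type sham kidneys, and a lower share of proximal tubule cells would raise the markers of all other cell types alike. Against that, the leukocyte median lay 1.49 above that of 48 podocyte, endothelial, collecting duct and loop of Henle genes (1.45 against -0.033; permutation p = 1e-05, the smallest that 1e+05 resamples can give). The permutation exchanged single genes as if independent, while the leukocyte list had an estimated inter-gene correlation of 0.818. Its p therefore does not cover the spread among animals. Such a loss alone, if equal along the whole proximal tubule, would also move its markers together. However, 8 of 16 lay more than 2 standard errors from their weighted mean of -0.56, 3 below and 5 above it. A loss of only part of the tubule could move them unequally and was not tested. A trend with coding length is argued against too, since with it removed the medians were 1.44 (camera adjusted p = 1.08e-15) for leukocyte markers and -0.342 (4.39e-05) for transporters. A hypothesis that stays open is more leukocytes with lower transporter expression in obese kidneys, and cell composition was not measured.

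Obese surgery replicate 3 lay nearest to the wild type sham libraries, at 0.517 on a scale from wild type sham (0) to obese sham (1) over 1635 genes, against 0.727 to 1.23 for the other 3 obese surgery libraries. Wild type sham libraries held out in turn lay at 0.0493 to 0.149, which argues against a wild type library under this label. Thinned to the lowest total of the 10 libraries it lay at 0.519, which argues against its depth as the cause. Mixing with wild type RNA would need a share of at least 28.5% to move another obese surgery library there, but of 14 genes at least 10-fold lower in obese sham than in wild type, 8 were under 0.5 of the level such a share brings (lowest Cyp8b1, 0.86 against 14 CPM) and 1 was above it (Tm4sf20, 6.67 against 3.87 CPM), which argues against mixing as the whole cause. Slc7a12 and LOC361914, both among the 8, had close levels (616 and 611 CPM in wild type sham) and may not be separate measures. Mixing would add its share of the wild type level to each gene. Over the 14 genes, levels were 1.75% to 49.1% of wild type, with a median of 13%. Cyp8b1, Serpinb12 and Cftr were at 1.75%, 2.85% and 5.47%. These low values argue against an admixture well above such shares, if the added RNA resembled the wild type libraries used here. An admixture of that small size and a stronger response to surgery in this rat stay open.

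Between obese surgery and obese sham, the median of oxidative phosphorylation genes was lower and that of immediate early genes higher at a correlation of 0.01, with 0 members of either past the edgeR threshold and adjusted p of 0.613 and 0.45 with an estimated correlation. The oxidative phosphorylation median lay at percentile 5.37 of random lists matched on coding length and abundance (-0.123 to 0.00579), so a shift of short or abundant genes stays open for it. The immediate early median lay at percentile 100 (matched lists -0.0844 to 0.0992), which argues against such a shift there. A single library decides each call: 9 of 10 refits kept the immediate early call, lost without obese surgery replicate 4 (median 0.224, adjusted p = 0.0682), and 9 of 10 kept the oxidative phosphorylation call, lost without obese surgery replicate 2 (0.0109, 0.872). In obese surgery replicate 2, mean levels relative to wild type sham were the lowest of all libraries for oxidative phosphorylation (-0.732), proximal tubule (-1.36) and transporter genes (-1.32). Whether these share a cause was not tested. Handling of single animals at collection stays open as an untested source, as does a response to surgery that differs between rats.

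Splits of the same libraries into other groups were run through the same tests. For obese sham against wild type sham, 1 of 10 splits, the real one, gave as many genes (974, highest other 0) and as many lists (16, highest other 15), and 10 splits are too few for a share under 0.05. For obese surgery against obese sham, chance cannot be excluded: 2 of 35 splits gave as many genes (3, highest other 20), and 28 of 35 as many lists (9, highest other 17), with at least 7 lists called in every split. The split with 20 genes set obese surgery replicates 3 and 4 with obese sham replicates 1 and 2 against the rest, which points to a structure of the samples beside the groups. For obese surgery against wild type sham, 2 of 35 splits gave as many genes (1143, highest other 1345) and 4 of 35 as many lists (16, highest other 17), so chance is not excluded by this count. The split with 1345 genes placed obese surgery replicate 3 with wild type libraries. For the F test, 2 of 100 drawn splits gave as many genes (813, highest other 835), a share under 0.05. The other split kept the wild type libraries together and mixed obese sham with obese surgery libraries. The count thus speaks at most to wild type against obese libraries, and it decides nothing about the division between the obese groups.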

How the results depend on the processing

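Settings chosen after seeing the data were header-count scaling, the robust quasi-likelihood fit, the length correction and leaving out obese surgery replicates 2 and 3 together. No refitted call of a named gene changed sign under any alternative, while counts past the threshold often changed. Of the 73 named genes and 41 lists past it, DESeq2 kept all 73 genes (its F test and the lists were not run), limma on log2(RPKM + 0.5) 70, limma without trend 62 genes and 39 lists, quantile normalization 65 and 31, and the replicate block 37 and 40. Refits without 1 library kept 46 to 72 genes and 36 to 41 lists. Of 3502 values past the threshold neither before nor after, 165 had the opposite sign. Median-of-ratios and header-count scaling, the low-count filters, summing models, the robust quasi-likelihood fit and the length correction changed no count of genes by more than 1.5-fold. Depth limits genes near 3 counts per library, and the spread within groups limits small changes. Where a value below differs, the cause was not tested, unless fewer libraries or an added term explain it by construction.

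The unaltered values were 974, 3 and 1143 genes for obese sham against wild type, surgery against obese sham and surgery against wild type, 813 by F test, and an opposite-sign share of 81.5%. With the replicate number as a block they were 218, 0, 382, 151 and 91.3%. Residuals of 8 pairs with the same number correlated at -0.43 to 0.077. This gives no sign that the numbers pair the libraries, but so few pairs cannot exclude it. limma on log2(RPKM + 0.5) gave a share of 84%. limma with a pseudocount of 0.1 called 0 genes for surgery against obese sham, with a share of 84.5%, and a pseudocount of 1 also gave 84.5%. limma without trend gave 572 genes for surgery against wild type, 431 by F test and 85.2%. Robust limma with array weights gave 1544 genes for obese sham against wild type, 1258 by F test and 77.3%. Quantile normalization gave 609 genes for surgery against wild type and 87.3%, and turned the oxidative phosphorylation median in obese sham against wild type to 0.051 (adjusted p = 0.748). Fits of only the groups compared gave 1635, 1 and 573 genes and 71.5%. DESeq2 gave 5 genes for surgery against obese sham, 1716 for surgery against wild type and 76.4%. Without obese surgery replicates 2 and 3 together, 1653 genes passed for obese sham against wild type, 1243 by F test, and the share was 75.9%. With the inter-gene correlation estimated, 0, 0 and 0 lists passed.

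Without 1 library at a time, counts were 377 (without obese sham replicate 3) to 1504 (without obese surgery replicate 2) for obese sham against wild type and 1 to 2 for surgery against obese sham. They were 317 (without wild type sham replicate 2) to 1832 (without obese surgery replicate 3) for surgery against wild type. The F test gave 226 to 1391 without the same 2 libraries. The share was 59.4% (without obese surgery replicate 3) to 92.7% (without obese sham replicate 1). For surgery against obese sham, the median of proximal tubule markers was -0.364 to -0.0441 and its test direction turned without obese surgery replicate 2 (adjusted p = 0.901). The median of extracellular matrix and fibrosis genes was -0.127 to 0.339, higher and past the threshold without obese sham replicate 3 (0.00301) or obese surgery replicate 3 (median 0.272, 0.0165). The median of tubular injury genes was -0.314 (without obese surgery replicate 2) to 0.403 (without replicate 3, adjusted p = 0.0155).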

Other observations

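The families below were chosen after the data were seen, and the tests of the androgen and solute carrier hypotheses before their values were. Families of genes sharing a name stem, some of them also in the fixed lists, were tested with camera at a correlation of 0.01 and BH adjustment over 60 tests. In obese sham against wild type sham kidneys, pattern recognition and leukocyte surface families were higher. Toll-like receptors, which sense microbial and tissue damage products, had 5 of 9 genes higher (median 1.16, camera adjusted p = 3.14e-06; 0.13 with an estimated correlation), led by Tlr1, Tlr7, Tlr2 and Tlr4. Chemokines of the Cxcl and Ccl families had 8 of 19 higher (1.17, adjusted p = 1.9e-05; 0.381 with an estimated correlation). Genes named for Fc receptors or related proteins, led by Fcer1g, Fcgr2b, Fcrls and Fcgr1a, had 5 of 8 higher (1.31, adjusted p = 0.000135; 0.381 with an estimated correlation). Matrix metalloproteinases had 5 of 13 higher (1.03, adjusted p = 0.00126; 0.381 with an estimated correlation), led by Mmp13, Mmp7, Mmp14 and Mmp12.

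Cytochrome P450 genes, of steroid, fatty acid and drug oxidation, had 12 of 39 lower and 1 higher in obese sham kidneys (median -0.13, camera adjusted p = 4.95e-06; 0.156 with an estimated correlation). Mitochondrial ribosomal proteins had 2 of 66 lower (-0.24, adjusted p = 3e-04; 0.517 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.073 there (adjusted p = 0.131) and of -0.12 in obese surgery against obese sham (adjusted p = 8.73e-05; 0.528 with an estimated correlation), with 0 of 75 genes past the edgeR threshold.

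Slco1a1, Cyp2c11, Cyp4a2 and Slc7a13, all lower in obese sham kidneys, are genes whose levels differ between the sexes in rodents, and a hypothesis is a lower androgen response. The median of 5 other androgen-responsive kidney genes was -0.42, at percentile 1.05 of matched random lists, where the prediction had been under 2.5. Odc1, the polyamine synthesis enzyme gene, fell by 1.67 ± 0.35 (edgeR adjusted p = 0.0143), while Gusb, the beta-glucuronidase gene, rose by 0.60 ± 0.16 (edgeR adjusted p = 0.0423). With members past the threshold in both directions the test decides nothing, a rule added after these values were seen. The sex of the rats is not given in the sources used here.

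A second hypothesis was that solute carriers outside the fixed lists are lower too in obese sham kidneys. The median of 213 such genes was -0.091, at percentile 0.02 of 10000 matched random lists, with 18 lower and 5 higher past the edgeR threshold. The prediction, a median under percentile 2.5, was met, though the median is small. By the rule added later for the androgen genes this test decides nothing either, since members past the threshold go both ways.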
